A study of Citrullus lanatus with 3 samples.

How the data were processed

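Total RNA was extracted with Trizol and had an RNA integrity number above 7, per the labels' protocols. There is 1 library for each of the 3 time points. The group of each library was taken from its label, and each column of the deposited tables was matched to a library by the library's title. The genome build, the gene annotation and the program that called circRNAs are not given in the sources used here. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0, without saying which file each made. Coordinates are those of the deposited tables. Gene identifiers beginning with Cla are reference genes, and identifiers beginning with MSTRG are loci that StringTie assembles from reads. Gene names and functions come from the annotation text deposited with each locus. A locus that joins several reference genes carries all their identifiers.

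The gene and transcript values are FPKM as the authors deposited them. The deposited transcript table also gives the coverage of each transcript, which is the number of aligned bases divided by its length. Within each library, coverage divided by FPKM was the same for every transcript above 0.5 FPKM, at 11.4, 10.7 and 0.413 for 0 h, 48 h and 25 d, so the depth behind each FPKM value is known. The authors deposited whole-number counts of back-splice junction reads per circRNA, and beside them SRPBM, the same counts scaled to a common number of reads. Dividing one by the other gave the reads behind each library, 13.7 times fewer at 25 d than at 0 h. Whether these are sequenced or mapped reads was not established here. Bases aligned to the assembled transcripts came to 69.1, 76.7 and 33.8 per such read.

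The number of read-pair equivalents of a locus was its aligned bases (coverage times length, summed over transcripts) divided by the aligned length of a read pair. That length was read from the base totals of single-exon transcripts alone in their locus, and was 300, 300 and 302 bases. A 95% counting interval of a fold is the exact conditional interval of 2 Poisson counts, taken from read-pair equivalents without a pseudocount. Read-pair equivalents are sums over estimated transcript values and reads carry no molecular identifiers, so intervals cover counting error only. They say nothing of the spread between plants. Counts past a fold threshold that counting error alone gives were simulated by drawing Poisson read pairs for both libraries from the levels of the second one, 20 times. The loci drawn were those kept by the filter on all 3 libraries, so loci that chance reads brought past it are not covered.

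The choices that follow were made before the data were examined. A log2 ratio is that of FPKM plus a pseudocount of 1, which understates the change of low genes. Loci with a mean of at least 1 FPKM over the 3 libraries were kept, which left 18238 of 22225 and set aside 3987. A locus was counted as higher or lower at a ratio of at least 2-fold on that scale. With 1 library per group no test of the conditions was possible, and thresholds describe these libraries. The 35 gene lists were search patterns for pathways, transcription factor families and markers of other leaf cell types, applied to the annotation text. A list's median log2 ratio was placed among the medians of 10000 random lists of annotated loci with the same number of genes in each of 10 bins of mean expression. A list is called when its median lies in the bottom or top 2.5%. Annotated loci numbered 14030 after the filter. The genes to be named were, per comparison, the 8 largest and 8 smallest log2 ratios among genes with an informative annotation and a mean of at least 5 FPKM. To these came the 2 members with the largest differences of each called list and of 7 lists that were always to be described. Among circRNAs these are the 5 highest values and the 3 largest differences in each direction. The locus MSTRG.19294, the circRNA host Cla002881 and genes named for a comparison in which the rule does not pick them were chosen after their values were seen.

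Alternatives were a pseudocount of 0.1 or 5, no filter on low values or a mean of at least 5 FPKM, median-of-ratios scaling, the same FPKM total in each library, the sum of the transcript table per locus and a fold threshold of 4. For circRNAs they were a minimum at the median detected value, the same circRNA total and detection in both libraries. Chosen after the data were seen were list members matched on the product name, loci with at least 50 read-pair equivalents, leaving out the 10 loci with the most aligned bases, 40S and 60S ribosomal names only, and circRNA reads per aligned base. KEGG pathways with at least 10 measured members, 122 in all, were also placed among matched random lists, and lists of antenna proteins, ethylene-responsive transcription factors and organelle-encoded protein names were added, after the data were seen. No authors' table of comparisons was used here, and viral RNA was not analysed here.

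The computations were tested on simulated read pairs with 50 loci changed in each direction at each fold. In 48 h against 0 h (18147 loci), 98.0% of loci raised 3-fold and 76.0% of those lowered 3-fold passed the 2-fold threshold, and 100% and 98.0% of those raised and lowered 8-fold. In 25 d against 0 h (18147 loci) these shares were 98.0%, 88.0%, 100% and 98.0%. In 25 d against 48 h (18174 loci) they were 78.0%, 76.0%, 100% and 94.0%. Counting intervals of unchanged loci held a ratio of 1 in 95.3%, 96.7% and 96.5% of cases for the 3 comparisons in that order. Of 100 random lists of 40 unchanged loci, 3, 6 and 4 lay past the percentiles, and all 20 lists raised 1.5-fold did in each comparison. Unchanged simulated loci differed by counting error alone, each drawn independently. The measured ratios spread more widely, with quartiles of −0.85 and 0.67 at 25 d against 0 h, and members of a real list may vary together. These list results therefore check the computation and do not give the error rate of the list calls. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.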

Results

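Leaves of watermelon (Citrullus lanatus), taken at an early true-leaf stage, were sampled at 0 h, 48 h and 25 d after inoculation with cucumber green mottle mosaic virus (CGMMV). CGMMV is a tobamovirus, a rod-shaped single-stranded RNA virus that infects cucurbits systemically. The study asked which genes, long noncoding RNAs and circular RNAs (circRNAs) respond to the virus. One total RNA library was sequenced per time point, 3 libraries in all, so no difference has a replicate check and no p-value across genes is given. Leaves inoculated without virus at 48 h or 25 d were not analysed here, so each comparison combines the virus, the inoculation, the time of sampling and leaf age. The tables hold 22225 loci with 37453 transcripts, in FPKM (fragments scaled by transcript length and library size). They also hold 616 circRNAs with their back-splice junction reads. The 0 h and 48 h libraries had 10.6 and 9.74 gigabases aligned to the assembled transcripts, and the 25 d library had 0.379 gigabases, 28.1 times fewer than at 0 h. The median locus was covered by 443, 410 and 13.8 read-pair equivalents at 0 h, 48 h and 25 d. Aligned base totals of lone single-exon transcripts piled up at 300 bases in the 0 h and 48 h libraries and at 302 bases in the 25 d library. The 25 d library was therefore read at, or trimmed to, another length. Whether it came from another sequencing run was not established, and such a run could not be told apart from the time point. Across the 18238 loci with a mean of at least 1 FPKM, log2 values correlated with a Pearson r of 0.940 between 48 h and 0 h. The r was 0.688 between 25 d and 0 h and 0.744 between 25 d and 48 h; these are correlations across loci, which are not independent replicates.

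At 48 h after inoculation, the genes with the largest ratios over 0 h included defence and hormone genes. Medians of the defence lists that were called higher ran from 0.18 to 0.50 on the log2 scale. The RNA silencing list (−0.042) and the receptor-like kinases (−0.017) were not called. The 0.18 is that of the pathogenesis-related list, whose median was −0.0062 with members matched on product names alone. Genes picked as the largest exceed a list median by selection. The largest difference among annotated genes was in Cla001623 (chromosome 2, 8310905 to 8311396), a pathogenesis-related protein 1a gene, which is a marker of salicylic acid-dependent defence. It had 56.8 FPKM at 48 h and 0.71 FPKM at 0 h, a log2 ratio of 5.08 with a pseudocount of 1 FPKM. Cla021554, a proteinase inhibitor I-B (chromosome 5, 4103524 to 4104188), had 66.6 against 1.62 FPKM, and Cla016932, a jasmonate-induced protein (chromosome 11, 26274965 to 26276233), had 279 against 10.1 FPKM. Cla010665 (chromosome 7, 28685211 to 28689296), an oxidase of the last step of ethylene synthesis, had 157 against 13.4 FPKM. Also among the 8 largest ratios were Cla002538, a phytase (68.3 against 3.68 FPKM), Cla017829, a peroxidase (67.8 against 4.81 FPKM), Cla018352, a threonine dehydratase (53.0 against 4.89 FPKM), and Cla018162, a glutathione S-transferase (23.7 against 1.82 FPKM). Counting error was small beside these differences. The 95% counting interval of the log2 FPKM ratio, with no pseudocount, ran from 5.57 to 7.27 for Cla001623 and from 4.61 to 4.98 for Cla016932.

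The jasmonate list, which holds enzymes and regulators of jasmonate synthesis and signalling, had a median log2 ratio of 0.47 at 48 h against 0 h. Of its 29 measured members, 11 were at least 2-fold higher and 0 at least 2-fold lower. Its Cla008517, a lipoxygenase (chromosome 2, 33543209 to 33549359), had 177 against 23.6 FPKM. The salicylic acid list had a median of 0.50, with 5 of 18 members at least 2-fold higher and 1 lower. Its pattern takes up any methylesterase, pectin methylesterases included, and phenylalanine ammonia-lyases, which the list of phenolic metabolism also holds. The list is therefore not particular to salicylic acid. Its members moved apart, since the phenylalanine ammonia-lyase gene Cla008727 had 1.80 against 30.0 FPKM, while Cla018299, of the same annotation, had 4.29 against 1.05 FPKM. Among 45 WRKY transcription factors, a family that regulates defence genes, the median was 0.41, with 12 members at least 2-fold higher and 0 lower. Cla007656 (15.2 against 1.62 FPKM) and Cla014433 (16.4 against 3.50 FPKM) had the largest differences of that list. NAC transcription factors had a median of 0.30 (10 of 42 members at least 2-fold higher, 1 lower), with Cla013922 at 23.1 against 4.02 FPKM and Cla015772 at 5.02 against 0.485 FPKM. The ethylene list had a median of 0.26 (12 of 102 higher, 1 lower), where Cla007578, an ethylene-responsive transcription factor, had 7.05 against 0.365 FPKM. NBS-LRR genes, which encode intracellular immune receptors, had a median of 0.25. Of those 32 genes 2 were at least 2-fold higher and 1 lower. The largest difference of the list was that of the lower gene, Cla003652, with 0.765 against 3.05 FPKM, followed by Cla007904 with 15.4 against 6.47 FPKM. Each of these medians lay in the top 2.5% of medians from 10000 random lists matched on size and mean expression; lists in the top or bottom 2.5% are called below.

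Cytochrome P450 genes, enzymes of oxidative metabolism, were also higher at 48 h, with a median of 0.24; 17 of 95 members were at least 2-fold higher and 5 lower, and 33 had ratios below 0. The largest differences were those of Cla012528 (11.1 against 1.91 FPKM) and the allene oxide synthase Cla015969 (4.36 against 0.599 FPKM), an enzyme of jasmonate synthesis. The cytokinin and gibberellin list (median 0.19), the MYB list (0.13) and the proteasome and ubiquitin list (0.09) were called with smaller shifts. Of their 29, 120 and 444 members, 5, 8 and 4 were at least 2-fold higher and 3, 5 and 9 lower. In the first list Cla020839, a gibberellin-regulated gene, had 98.3 against 21.3 FPKM and Cla014721, a GID1-like gibberellin receptor, 39.2 against 9.82 FPKM. In the MYB list Cla017797 had 5.24 against 0.143 FPKM and Cla005982, a MYB-related factor, 13.0 against 2.01 FPKM. Cla002957, a ubiquitin-conjugating enzyme, had 9.31 against 1.31 FPKM, and the F-box gene Cla013403 had 4.67 against 20.4 FPKM. The proteasome itself went the other way: the 73 genes of the KEGG proteasome pathway had a median of −0.26, in the bottom 2.5%, with 60 of them below 0. The pathogenesis-related list had a median of 0.18 over 107 members, 15 of them at least 2-fold higher and 5 lower. That list had taken up ethylene-responsive transcription factors, whose annotation text mentions pathogenesis-related factors. With members matched on the product name alone, 42 genes remained and their median was −0.0062, at percentile 68.9. Its acidic chitinase Cla004920 had 13.4 against 1.22 FPKM.

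Photosystem and light-harvesting genes were lower at 48 h than at 0 h. The carbon fixation list was not called, with a median log2 ratio of 0.046 and 13 of 19 genes above 0. The median log2 ratio of the 53 photosystem and light-harvesting genes was −0.68; 21 of them were at least 2-fold lower and 0 at least 2-fold higher. The chlorophyll a-b binding proteins, which form the light-harvesting antenna, led this group. Cla015680 (chromosome 2, 2561386 to 2562576) had 152 against 2226 FPKM, Cla009753 (chromosome 1, 32602576 to 32603373) had 249 against 2494 FPKM, and Cla013483 (chromosome 2, 28901801 to 28902604) had 29.0 against 358 FPKM. The gene Cla015679, a pentatricopeptide repeat protein whose locus ends 2561529, overlaps Cla015680 and had 6.02 against 68.4 FPKM, so its value may share reads with its neighbour. In 46 of the 53 genes, 86.8%, the counting interval of the ratio lay below 1. The chlorophyll biosynthesis list had a median of −0.32, with 0 of 17 genes beyond 2-fold. In it, Cla023399, a protochlorophyllide reductase, had 138 against 254 FPKM, and Cla002769, a magnesium chelatase subunit, 52.6 against 76.4 FPKM. Plastid ribosomal proteins had a median of −0.29 and the cytosolic ribosomal list a median of −0.21. The ribosomal protein S9-like locus Cla004950;Cla004951, which both patterns took up, had 1.89 against 5.77 FPKM. Cla020131, a plastid-type ribosomal protein L25 gene, had 6.89 against 13.6 FPKM, and Cla018531, a ribonucleoprotein gene of the cytosolic list, 18.5 against 38.9 FPKM.

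Most clock genes were lower as well. Cla013783 (chromosome 8, 16621023 to 16630243), which encodes GIGANTEA, a clock protein whose transcript peaks late in the day, had 27.2 FPKM at 48 h and 92.1 FPKM at 0 h. Cla000304, a pseudo-response regulator 5 gene (chromosome 0, 23344792 to 23349307), had 18.9 against 44.9 FPKM. An early flowering 3 gene, Cla022663, went the other way, with 53.3 against 34.9 FPKM. The median over the 5 clock genes measured was −0.91, in the bottom 2.5%. The wider KEGG pathway of plant circadian rhythm, 116 genes, had a median of 0.044, at percentile 87.4, with 2 genes at least 2-fold higher and 12 lower. Other strongly lower genes were Cla015176, a 3-beta hydroxysteroid dehydrogenase (0.175 against 33.4 FPKM), Cla021808, a stress-responsive alpha-beta barrel protein (35.5 against 750 FPKM), and Cla004392, a UDP-glycosyltransferase 74 F1 (2.20 against 37.4 FPKM). Epidermis and cuticle markers (median −0.23), usual reference genes (−0.18) and cell wall remodelling genes (−0.13) were also in the bottom 2.5%, although Cla010775, a lipid transfer protein of the cuticle list, had 86.6 against 19.5 FPKM and the lipase-like Cla010402 11.5 against 2.16 FPKM. Of the reference genes, a tubulin beta gene, Cla007342, had 4.48 against 13.1 FPKM. In the cell wall list Cla015040, with no product name, had 25.2 against 6.12 FPKM, and the xyloglucan endotransglucosylase Cla007704 had 22.5 against 80.9 FPKM.

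Among all 18238 loci, 671 were at least 2-fold higher at 48 h than at 0 h and 604 at least 2-fold lower. Counting error alone, simulated at the depth of both libraries, gave 1.55 loci in each direction. The median over all loci was 0.0087. Of the 35 fixed lists, 11 were called higher and 8 lower, and the other 16 had medians between −0.12 and 0.09. A median near 0 can hide a skew of single members. Of 34 phloem and vascular markers 0 were at least 2-fold higher and 9 lower at 48 h (3 and 12 at 25 d against 0 h), and of 204 cell cycle and histone genes 0 were higher and 21 lower (18 and 50). With members matched on the product name alone, the cell cycle and histone list was called lower at 48 h, at −0.20 over 133 genes, and calcium signalling (0.099 over 94 genes) and carbon fixation (0.43 over 9 genes) were called higher. The cytokinin and gibberellin call ended with a pseudocount of 5 (median 0.084), with no filter on low values (0.0053) and with a mean of at least 5 FPKM (0.075). The salicylic acid call ended, at a median of 0.16, when only genes with a mean of at least 5 FPKM were kept.

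**Figure D1:**
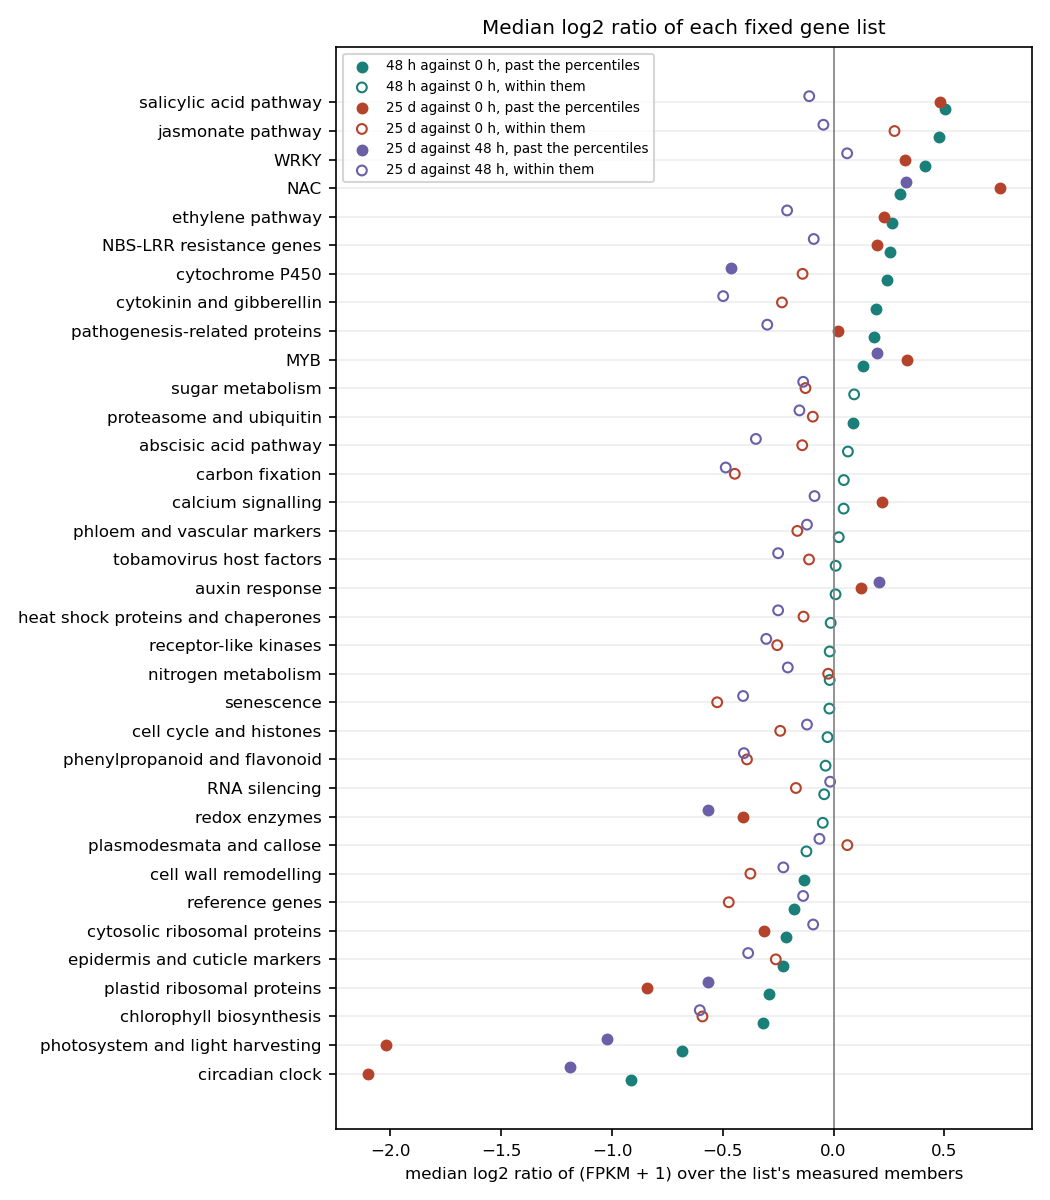
Median log2 ratio of (FPKM + 1) over the measured members of each of the 35 fixed gene lists (rows), for 48 h against 0 h, 25 d against 0 h and 25 d against 48 h (colours). Filled points lie in the top or bottom 2.5% of matched random lists and open points between; the photosystem and clock lists are the lowest in every comparison, at −0.68 and −0.91 for 48 h against 0 h.

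At 25 d after inoculation, 4 of the 8 annotated genes with the largest ratios over 0 h encoded transcription factors. Cla010793 (chromosome 7, 29930659 to 29932922), annotated as CONSTANS, a regulator of day-length responses, had 515 FPKM at 25 d and 0.848 FPKM at 0 h, a log2 ratio of 8.13. Cla007761 (chromosome 2, 997830 to 999818), a WRKY factor, had 482 against 2.66 FPKM. Cla021917, a NAC factor, had 213 against 2.49 FPKM, and Cla017850, a MYB factor, had 80.5 against 0.496 FPKM. Cla002321, annotated as a CLE-related peptide, a class of small signalling peptides, had 446 against 1.29 FPKM. The proteinase inhibitor Cla021554 was again far above 0 h, at 284 FPKM, as were the remorin Cla017458 (70.9 against 0.432 FPKM) and Cla003626, annotated as a splicing factor (618 against 12.6 FPKM). Pathogenesis-related protein 1a, Cla001623, had 74.8 FPKM. These values rest on few reads at 25 d. Cla010793 was covered by 754 read-pair equivalents, Cla021554 by 84 and Cla001623 by 50, and the counting interval of the log2 ratio of Cla001623 ran from 5.84 to 7.75.

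NAC factors had the highest list median at 25 d against 0 h, 0.75, with 10 of 42 genes at least 2-fold higher and 1 lower. WRKY factors had a median of 0.32 (16 of 45 at least 2-fold higher, 3 lower). The salicylic acid list (0.48), MYB factors (0.33), the ethylene list (0.23), calcium signalling genes (0.22), NBS-LRR genes (0.20) and auxin-response genes (0.12) had medians above 0 that turned negative under the scaling without the 10 most abundant loci described below. In that order 3, 30, 26, 22, 7 and 27 genes were at least 2-fold higher and 1, 19, 22, 21, 3 and 17 lower. With no filter on low values the salicylic acid (−0.031), ethylene (−0.022), calcium (−0.024), NBS-LRR (−0.0064) and auxin (−0.069) medians were also negative, and the salicylic acid call ended. Of the salicylic acid list, the phenylalanine ammonia-lyase Cla018297 had 65.2 against 23.3 FPKM, and Cla007802, a pectin methylesterase taken up by the pattern, 2.83 against 9.73 FPKM. Cla007802 rested on 2 read-pair equivalents at 25 d, and its log2 counting interval, −4.83 to 0.10, does not exclude an equal level. With a mean of at least 5 FPKM the salicylic acid call ended and its median was −0.045, at percentile 61.4, and the auxin call ended at 0.10, percentile 92.7. The NBS-LRR call ended with transcript sums, at 0.17 and percentile 97.4. In the other lists, the auxin-induced SAUR-like genes Cla016630 and Cla020821 had 207 against 16.9 FPKM and 33.8 against 0.167 FPKM, the latter from 14 read-pair equivalents at 25 d. The TIR-NBS-LRR gene Cla016986 had 13.7 against 2.32 FPKM and the TIR-NBS locus Cla012423;Cla012424 8.93 against 1.74 FPKM. The WRKY gene Cla019646 had 19.6 against 0.136 FPKM and the NAC gene Cla010201 19.4 against 1.52 FPKM. The ethylene-responsive factor Cla007578 had 16.2 FPKM, whereas Cla011389, of the same kind, was listed at 0 against 9.79 FPKM. Of the calcium list, the protein kinase gene Cla021521 was listed at 0 against 7.15 FPKM and the IQ-domain gene Cla007036 had 21.4 against 1.80 FPKM. On the deposited scale all of them were in the top 2.5% of matched lists. The pathogenesis-related list did so too, at 0.021, with 25 of 107 genes at least 2-fold higher and 29 lower, but its median was −0.44 with product names alone, at percentile 24.2, and it was also negative with the same FPKM total (−0.026) and without the 10 most abundant loci (−0.33). The jasmonate list, at 0.28 and percentile 97.3, was just within the percentiles, and with product names alone it was called, at 0.29 and percentile 97.9. The jasmonate-induced gene Cla016932 had 10.2 FPKM at 25 d, near its 10.1 FPKM at 0 h.

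Photosystem and light-harvesting genes were lower still at 25 d. The carbon fixation list was again not called at 25 d against 0 h, with a median of −0.45 at percentile 12.5. With product names alone its median was 0.15. Of the 53 photosystem and light-harvesting genes, 42 were at least 2-fold lower than at 0 h and 2 higher, with a median log2 ratio of −2.02. Cla017325, a chlorophyll a-b binding protein (chromosome 10, 17318803 to 17320717), had 16.9 against 655 FPKM, and Cla022963, another (chromosome 11, 15966048 to 15968684), had 69.4 against 988 FPKM. Plastid ribosomal proteins had a median of −0.84, with 44 of 106 at least 2-fold lower and 6 higher; the ribosomal protein L5 gene Cla002246 had 932 against 114 FPKM. The chlorophyll biosynthesis list, at −0.59 and percentile 6.71, was called lower only with product names alone, at −0.82. The clock list had a median of −2.10 over 5 genes, while the 116 genes of the KEGG circadian rhythm pathway had a median of 0.25, in the top 2.5%, with 26 at least 2-fold higher and 18 lower. GIGANTEA, Cla013783, was at 8.04 FPKM, and Cla000304 was at 3.45 FPKM. Cla004345, annotated as ELF4, a clock protein of the evening complex, had 1.88 against 180 FPKM. The opposite was seen in Cla018631, an At5g37260-like MYB gene, with 158 against 6.38 FPKM. Redox enzymes had a median of −0.41, with 69 of 184 at least 2-fold lower and 24 higher. The peroxidase Cla003191 had 6.88 against 265 FPKM, and the glutathione S-transferase Cla022390 was listed at 0, with a log2 ratio of −5.17. The cytosolic ribosomal list (median −0.31) was also below the percentiles, but it had taken up plastid-type names; with 40S and 60S names only its median was −0.18, at percentile 17.1. Its ribosomal protein L7a gene Cla002365 had 267 against 17.9 FPKM.

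Of the single genes lowest at 25 d, Cla011165, a germin-like protein (chromosome 3, 25895838 to 25897005), had 7.07 against 1328 FPKM. Several others were listed at 0 at 25 d: Cla003912, a dnaJ chaperone with 227 FPKM at 0 h, the merged locus Cla003232;Cla003233, a light-regulated protein with 139 FPKM, Cla005657, a cortical cell-delineating protein with 113 FPKM, Cla001439, a phloem filament protein with 103 FPKM, Cla008126, a CONSTANS-like zinc finger protein with 64.4 FPKM, and Cla001307;Cla001308, an intracellular protease locus with 56.5 FPKM. A tubulin-specific chaperone, Cla006982, and a 50S ribosomal protein, Cla012232, were listed at 0 there as well, with 13.6 and 13.3 FPKM at 0 h and 8.33 and 13.5 FPKM at 48 h. At the level of 0 h these 2 genes would have had 9.62 and 11.2 read-pair equivalents at 25 d, and the upper counting bounds of their log2 ratios were −1.37 and −1.60. For Cla003912 and Cla003232;Cla003233, 209 and 381 would be expected and the bounds were −5.83 and −6.69. These bounds cover counting error only. The locus Cla006458;Cla006457 of the reference list, with no product name, had 53.6 against 5.90 FPKM. Of the 18238 loci kept by the filter, 1182 were listed at 0 at 25 d and 91 at 0 h.

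Among the 18238 loci, 3356 were at least 2-fold higher at 25 d than at 0 h and 3927 at least 2-fold lower; counting error alone gave 289 and 961 at these depths. The direction of most list medians above 0 depends on the scale of the library. When the 10 loci with the most aligned bases were left out and the rest rescaled to the same total, the median of all loci moved from −0.074 to −0.53. The split changed to 2219 higher and 6025 lower. With other settings the split turned the other way. It was 2046 higher and 1647 lower with a pseudocount of 5, and 1369 and 1219 with a fold threshold of 4. Without those 10 loci the lists named above stayed in the top 2.5% of matched lists, but that scaling moves the random lists alike. Their percentiles could therefore hardly change. The NAC and WRKY medians stayed above 0 without those loci.

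**Figure D2:**
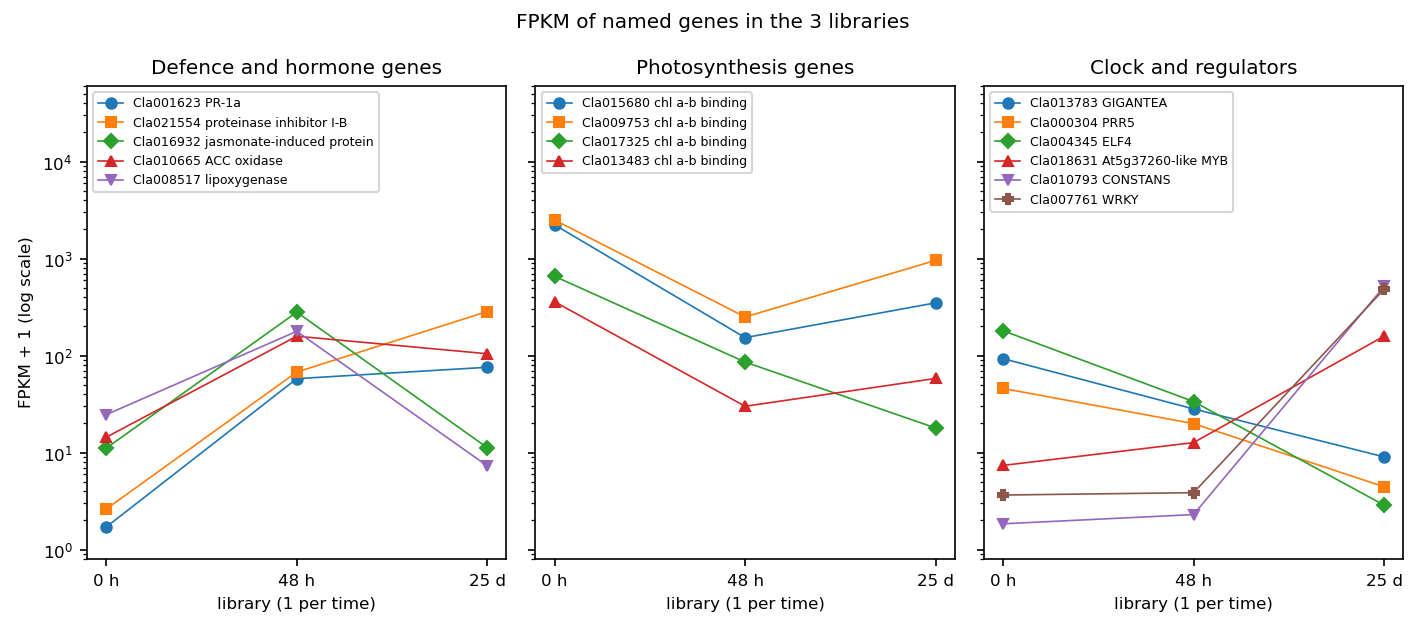
FPKM + 1 on a log axis in the 3 libraries (0 h, 48 h and 25 d, 1 library each) for named defence and hormone genes (left), chlorophyll a-b binding proteins (middle) and clock genes and other regulators (right). Cla016932 and Cla008517 were highest at 48 h (279 and 177 FPKM), and Cla010793 and Cla007761 were near 1 to 3 FPKM until 48 h and at 515 and 482 FPKM at 25 d.

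Between 48 h and 25 d, Cla010793 (515 FPKM at 25 d, log2 ratio 7.81), Cla002321 (446 against 1.15 FPKM), the NAC gene Cla021917 (213 against 0.631 FPKM) and the WRKY gene Cla007761 (482 against 2.87 FPKM) had the largest ratios, all higher at 25 d. Cla002858 (chromosome 8, 14058122 to 14058892), a GUN4-like gene, whose product stimulates chlorophyll precursor synthesis, had 4381 against 82.5 FPKM. Cla015192, a sterol C-24 reductase, had 560 against 12.5 FPKM, Cla003626 618 against 13.2 FPKM, and Cla005214, a pectinesterase, 45.2 against 0.166 FPKM. Some genes high at 48 h were lower or listed at 0 at 25 d. The phytase Cla002538, the peroxidase Cla001849 and the thaumatin-like gene Cla011476 were listed at 0, against 68.3, 28.7 and 8.74 FPKM at 48 h. So were Cla003912 and Cla005657, against 61.4 and 35.2 FPKM, and 3 genes with 27.4, 26.9 and 26.4 FPKM at 48 h: Cla009044, named only after a cDNA clone, Cla017756, a nucleoside transporter, and Cla015396, named only after an Arabidopsis locus. The germin-like gene Cla011165 had 7.07 against 287 FPKM.

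Of the fixed lists, NAC (median 0.32), auxin response (0.21) and MYB (0.20) lay above the percentiles at 25 d against 48 h, and all 3 medians fell below 0 under the scaling without the 10 most abundant loci. Of their 42, 121 and 120 genes, 6, 26 and 23 were at least 2-fold higher and 5, 15 and 19 lower. With no filter on low values the MYB call ended, at −0.12, and the auxin median was −0.033. The MYB gene Cla017850 had 80.5 FPKM at 25 d and a log2 ratio of 5.03, and Cla004910 was listed at 0 against 14.4 FPKM. The auxin-induced genes Cla016630 and Cla020821 had 207 against 22.9 FPKM and 33.8 against 0.288 FPKM, and the NAC gene Cla015772 was listed at 0 against 5.02 FPKM. The photosystem list had a median of −1.02, with 27 of 53 genes at least 2-fold lower and 6 higher. Within it, Cla016851, a photosystem II subunit X gene, had 51.3 against 341 FPKM, whereas Cla018600, a chlorophyll a-b binding protein, had 118 against 5.58 FPKM. The clock list (−1.19), redox enzymes (−0.57), plastid ribosomal proteins (−0.57) and cytochrome P450 genes (−0.46) lay below the percentiles. At least 2-fold lower in these were 4 of 5, 68 of 184, 33 of 106 and 30 of 95 genes, and 0, 17, 6 and 9 were higher. The glutaredoxin C4 gene Cla018876 and the P450 gene Cla005018 were listed at 0 against 18.4 and 5.33 FPKM, and another P450 gene, Cla023293, had 2.71 against 17.7 FPKM. Cla002246, the ribosomal protein L5 gene, had 932 against 85.3 FPKM. The P450 call, at percentile 2.24, ended under 5 of the alternatives tried. Lists within the percentiles included pathogenesis-related proteins, WRKY, NBS-LRR and reference genes. In these, Cla020969, an ethylene-responsive factor, was listed at 0 against 6.22 FPKM, and the WRKY gene Cla019646 had 19.6 against 0.255 FPKM. Cla004211, a disease resistance gene, had 1.14 against 6.31 FPKM, the TIR-NBS gene Cla019863 12.4 against 4.09 FPKM and the tubulin beta gene Cla011450 2.83 against 15.6 FPKM. Cla004211 rested on 1 read-pair equivalent at 25 d, and its log2 counting interval, −7.79 to 0.029, does not exclude an equal level. In all, 2722 loci were at least 2-fold higher and 3412 at least 2-fold lower, where counting error alone gave 284 and 966. Without the 10 most abundant loci the split was 1801 higher and 5712 lower, and the median of all loci moved from −0.11 to −0.56. The split turned to 1665 higher and 1176 lower with a pseudocount of 5, and to 1130 and 781 with a fold threshold of 4.

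The lists closest to the virus itself stood within the percentiles in all 3 comparisons. The RNA silencing list, the small-RNA machinery that cuts viral RNA, had medians of −0.042, −0.17 and −0.016 over its 17 members at 48 h against 0 h, 25 d against 0 h and 25 d against 48 h. An ARGONAUTE 1 gene, Cla010213, had 9.93, 6.31 and 6.98 FPKM at 0 h, 48 h and 25 d, and the RNA-dependent RNA polymerase locus Cla011269;Cla011270 had 5.74, 8.99 and 3.62 FPKM. The Dicer-like locus Cla009537;Cla009539;Cla009540 had 5.64, 5.38 and 21.9 FPKM at 0 h, 48 h and 25 d, and the ribonuclease 3-like locus Cla021060;Cla021061 had 12.4, 15.6 and 88.5 FPKM. The host factors of tobamovirus replication had medians of 0.0095, −0.11 and −0.25 over 19 members. With members matched on the product name alone, 10 remained and the medians were 0.0058, 0.17 and 0.065, still within the percentiles. The tobamovirus multiplication 1 locus Cla012853;Cla012854 had 8.51, 9.21 and 1.21 FPKM, the last from 2 read-pair equivalents. An elongation factor 1-alpha gene, Cla004729, had 4.91, 11.7 and 11.7 FPKM. A heat shock protein gene, Cla011362, had 61.7, 25.4 and 15.5 FPKM. The list had also taken up mitochondrial import receptor genes such as Cla004074, with 20.4, 18.1 and 108 FPKM, through a shared abbreviation.

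Loci assembled from the reads with no reference gene name, a class that may hold long noncoding RNAs among others, numbered 2162 at a mean of at least 1 FPKM. Outside this class, 2311 of all 22225 loci had a gene name but no annotation text, and long noncoding RNAs may lie there too. At 48 h against 0 h, 129 of the 2162 loci were at least 2-fold higher and 45 lower. At 25 d against 0 h, 884 were higher and 354 lower, where counting error alone gave 101 and 283. Transcripts at these loci split by exons: of 1538 with a single exon 773 were higher and 207 lower (median 1.01), whereas of 1017 with several exons 226 were higher and 303 lower (median −0.15). Transcripts within introns of reference genes, 290 in all, had a median of 1.47, and antisense transcripts, 280 in all, a median of −0.77, with 41 higher and 124 lower. At 25 d against 48 h the counts were 766 and 391. The most abundant locus of all, MSTRG.19294 (chromosome 9, 31125642 to 31494636), carries no annotation and took 15.9%, 16.0% and 10.4% of the aligned bases at 0 h, 48 h and 25 d. Of 1817 single-exon transcripts at unknown loci, 1462 had no strand, so sense and antisense transcripts at those loci cannot be told apart.

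**Figure D3:**
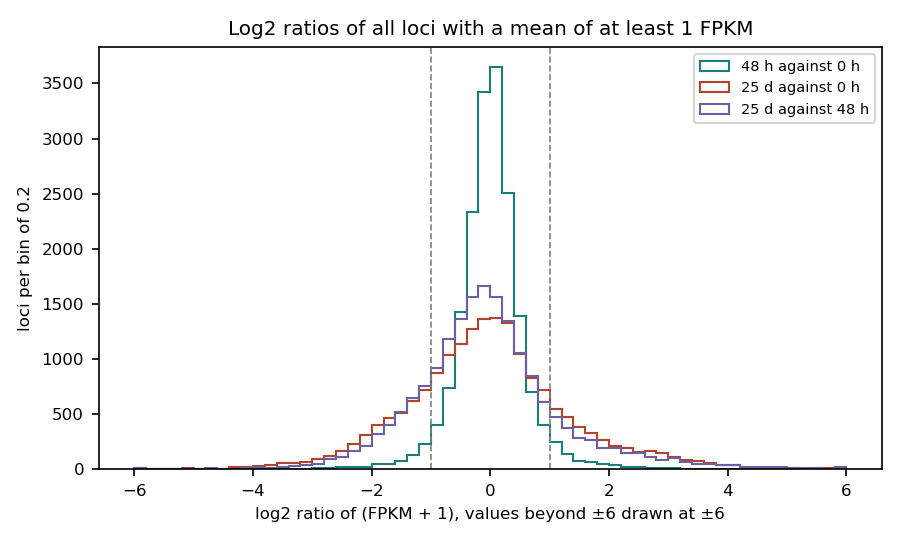
Number of loci per bin of log2 ratio of (FPKM + 1), over the 18238 loci with a mean of at least 1 FPKM, for the 3 comparisons; dashed lines mark 2-fold. The ratios for 25 d are spread more widely than those for 48 h against 0 h, with 3356 and 3927 loci beyond 2-fold for 25 d against 0 h and 671 and 604 for 48 h against 0 h.

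The circRNA table held 616 circRNAs, 597 made of exons and 19 of introns, from 535 host genes. The 0 h, 48 h and 25 d libraries had 345, 340 and 19 of them, from 688, 712 and 26 junction reads. In 378 of the 616, a single read over all libraries was the whole evidence, and 5 circRNAs were seen in all 3 libraries. The glutamate synthase gene Cla002881 gave the most, 5 circRNAs. At 0 h the most reads came from circRNA176 (chromosome 1, 7178073 to 7178432), from the acid phosphatase gene Cla005814, with 43, 29 and 0 reads at 0 h, 48 h and 25 d. circRNA263 (chromosome 8, 16628250 to 16628843), made of 2 exons of the GIGANTEA gene Cla013783, had 33, 24 and 4 reads. In SRPBM, junction reads scaled to a common number of reads, its level was 214, 189 and 357, the last from 4 reads (95% counting interval 97.2 to 914). At 48 h against 0 h its ratio was 0.881 (95% counting interval 0.498 to 1.54), while its host gene had 27.2 against 92.1 FPKM. circRNA204 and circRNA113, from 2 genes annotated as Arf-GAP proteins, Cla009828 and Cla002665, had 24, 30 and 0 and 28, 23 and 0 reads. circRNA299 (chromosome 10, 1039240 to 1040362), from Cla008835, a poly polymerase domain gene, had 6, 7 and 3 reads and was at 268 SRPBM at 25 d, the 3rd highest value.

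Between 48 h and 0 h, 286 circRNAs were at least 2-fold higher and 271 at least 2-fold lower, but only 79 were seen in both libraries. Of 606 circRNAs in either library, the counting interval of the ratio excluded 1 for 3 higher ones and 1 lower one. No allowance was made for the number of intervals. The higher ones included circRNA97 (chromosome 4, 23387790 to 23388516), from Cla018570, an activating signal cointegrator gene, with 22 against 6 reads. They also included circRNA258 (chromosome 8, 8982608 to 8982928), from Cla003692, a choline/ethanolamine kinase gene, with 11 against 1 read. The lower one was circRNA327 (chromosome 10, 24188962 to 24196706), from Cla017581, a ubiquitin carboxyl-terminal hydrolase gene, with 0 against 7 reads. circRNA197 (chromosome 1, 29444625 to 29446581), from the beta-galactosidase gene Cla014254, had 1 against 8 reads, with a ratio interval of 0.00341 to 1.13. At 25 d, 17 circRNAs were at least 2-fold higher and 338 lower than at 0 h, and 17 higher and 333 lower than at 48 h. Circular RNAs in either library numbered 357 for 25 d and 0 h and 352 for 25 d and 48 h. The counting interval of the ratio lay above 1 for 3 of them against 0 h and for 2 against 48 h, and below 1 for 0 in both. The 3 were circRNA299, with 268 against 39.0 SRPBM (ratio 6.87, interval 1.11 to 32.2), circRNA11 (chromosome 7, 18892928 to 18894438) and circRNA593 (chromosome 1, 4381298 to 4381698). circRNA11, from the splicing factor gene Cla014668, had 1, 0 and 2 reads, and circRNA593, from Cla002353, a gene annotated as a lipid A export permease, had 0, 0 and 2 reads. Against 48 h the ratio of circRNA299 was 4.86 (0.811 to 21.3). A count of 0 at 25 d allows up to 329 SRPBM by its 95% counting interval, above the 279 of circRNA176 at 0 h, whose ratio interval ran from 0 to 1.23. All circRNAs together had 4469, 5604 and 2320 SRPBM. The 25 d total was 0.519 times that at 0 h (counting interval 0.337 to 0.767). Per gigabase aligned to the assembled transcripts, the totals were 64.7, 73.1 and 68.6, and the 25 d to 0 h ratio was 1.06 (0.688 to 1.57). Intervals cover counting error only.

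**Figure D4:**
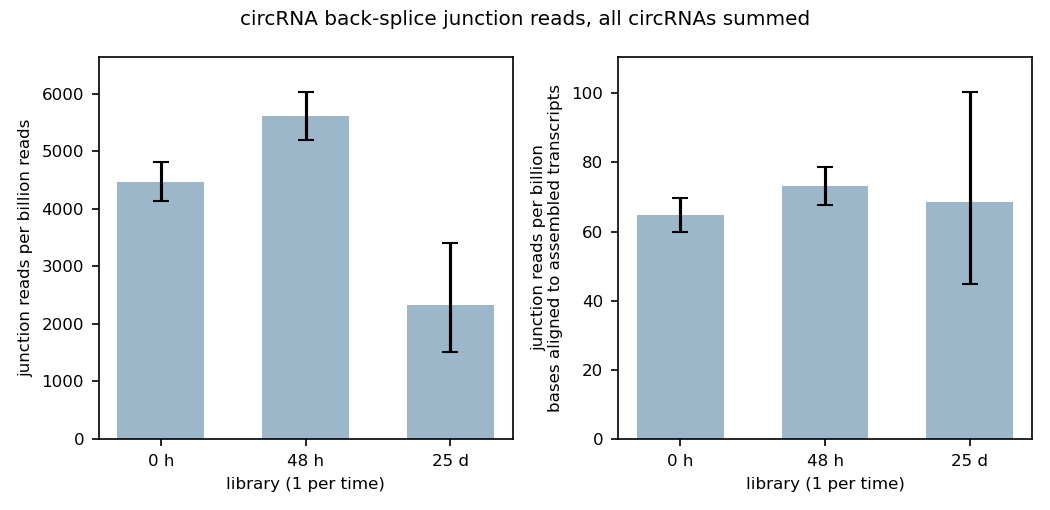
Junction reads of all circRNAs summed in each library (0 h, 48 h and 25 d, 1 library each), in SRPBM (left) and per gigabase aligned to assembled transcripts (right). Bars are the values and whiskers the exact 95% Poisson intervals; the 25 d bar is 2320 on the left, below the others, and 68.6 on the right, between them.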

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

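Matching list members on the product name, leaving out the 10 loci with the most aligned bases, keeping loci with at least 50 read-pair equivalents, and using 40S and 60S names only were chosen after the data were seen. So was scaling circRNA reads by aligned bases. No paired analysis was possible because each time point has 1 library, and for the same reason no library could be left out. The cause of a change was not tested unless the alternative's construction shows it. Of 371 results for called lists under the alternatives, 337 kept their sign and their side of the percentiles. A scaling moves a list and its random lists alike, so the scalings among these could hardly change a percentile. Counts of loci stayed within 1.5 times the reported count in 34 of 60 cases, counts of unannotated loci in 35 of 54 and counts of circRNAs in 17 of 24. Of 786 values for named genes with a reported ratio of at least 2-fold, 0 changed sign. This was largely fixed in advance, since a pseudocount cannot turn a sign and the scalings were too small to turn a 2-fold ratio. Of 816 values for named genes, 162 moved further than the counting error of the reported ratio. The photosystem list stayed in the bottom 2.5% in all 3 comparisons under each alternative.

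A larger pseudocount, a higher filter and a larger fold threshold lower the counts by construction. In the order higher and lower, a pseudocount of 0.1 gave 1136 and 1053 loci at 48 h against 0 h, of which 283 and 127 were unannotated. A pseudocount of 5 gave 223 and 236 (unannotated 31 and 9), 2046 and 1647 at 25 d against 0 h (unannotated lower 87), and 1665 and 1176 at 25 d against 48 h (unannotated lower 85). With a mean of at least 5 FPKM the counts were 412 and 358 at 48 h against 0 h (unannotated 57 and 18), 2027 and 2137 at 25 d against 0 h (428 and 86), and 1568 and 1820 at 25 d against 48 h (377 and 100). A fold threshold of 4 gave 114 and 80 (unannotated 19 and 4), 1369 and 1219 (529 and 109), and 1130 and 781 (470 and 112), in the same order of comparisons. With no filter, 591 unannotated loci were lower at 25 d against 48 h. Leaving out the 10 loci with the most aligned bases gave 2219 and 6025 at 25 d against 0 h, and 1801 and 5712 at 25 d against 48 h. With at least 50 read-pair equivalents, 2041 loci were higher and 3542 lower at 25 d than at 0 h, and 1541 and 2964 than at 48 h. The higher ones were thus 36.6% and 34.2% of the loci beyond 2-fold, against 46.1% and 44.4% as reported. That filter sums the pairs of both libraries and so mostly drops loci low in the deeper one. A lower share of higher loci follows in part by construction.

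Leaving out those 10 loci lowered the 25 d values relative to the other libraries. At 25 d against 0 h the list medians became −0.33 for pathogenesis-related proteins, −0.15 for NBS-LRR genes, −0.0024 for salicylic acid, −0.26 for ethylene, −0.36 for auxin, −0.099 for MYB and −0.27 for calcium signalling. At 25 d against 48 h they became −0.23 for auxin, −0.093 for NAC and −0.25 for MYB. All of these lists stayed in the top 2.5%, which is no check of the calls, since the scaling moves the random lists alike. With no filter, medians at 25 d against 0 h were −0.16 for pathogenesis-related proteins, −0.0064 for NBS-LRR genes, −0.031 for salicylic acid, −0.022 for ethylene, −0.069 for auxin and −0.024 for calcium signalling, and at 25 d against 48 h −0.033 for auxin and −0.12 for MYB. Of these, the calls of pathogenesis-related proteins, salicylic acid and MYB ended. The same FPKM total gave −0.026 for pathogenesis-related proteins at 25 d against 0 h. Product names alone gave −0.0062 for that list at 48 h and −0.44 at 25 d against 0 h, because the ethylene-responsive factors drop out. Product names alone also made 7 calls that the whole annotation text did not give. At 48 h these were carbon fixation (0.43) and calcium signalling (0.099), higher, and cell cycle and histones (−0.20), lower. At 25 d against 0 h they were jasmonate (0.29), higher, and chlorophyll biosynthesis (−0.82), lower. At 25 d against 48 h calcium signalling (0.013, from −0.086) and reference genes (0.12, from −0.14) were called higher with a change of sign.

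Some calls ended without a change of sign. The P450 median at 25 d against 48 h was −0.53 with a pseudocount of 0.1, −0.23 with 5, −0.28 with no filter, −0.41 with median-of-ratios scaling and −0.85 without the 10 loci. The cytokinin and gibberellin median at 48 h was 0.084 with a pseudocount of 5, 0.0053 with no filter and 0.075 with a mean of at least 5 FPKM. That filter also took the salicylic acid median to 0.16 at 48 h, the auxin median to 0.10 at 25 d against 0 h and, with a change of sign, the salicylic acid median to −0.045 at 25 d against 0 h. The transcript sums gave 0.17 for NBS-LRR genes at 25 d against 0 h, and 40S and 60S names only gave −0.18 for cytosolic ribosomal proteins.

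For circRNAs, a minimum at the median detected value left 88 lower at 48 h. Only circRNAs seen in both libraries gave 25 higher and 5 lower at 48 h, 5 and 0 at 25 d against 0 h, and 5 and 0 at 25 d against 48 h, because most circRNAs were seen in 1 library. Depth limits the 25 d library most: 7852 loci had under 10 read-pair equivalents there, against 640 at 0 h and 567 at 48 h.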

Other observations

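The tests of time of day, of loci without a reference gene name and of circRNA totals were chosen after the results were seen, as were the KEGG pathways and the organelle list; the tests of counting error and library scaling for the photosystem genes were written before their values were computed. The test of intronic transcripts was written beforehand for the organelle-like names only. Of 122 KEGG pathways, 14 were called higher and 25 lower at 48 h against 0 h, 10 and 21 at 25 d against 0 h, and 8 and 14 at 25 d against 48 h. The pathways named here were picked after their values were seen. Among them, flavone and flavonol biosynthesis (12 genes) had a median log2 ratio of 0.60 at 48 h and 0.72 at 25 d against 0 h, at percentiles 100 and 99.7. Linoleic acid metabolism (23 genes), which includes lipoxygenases, had 0.32 and 0.43, at percentiles 99.9 and 99.4. DNA replication (68 genes) had −0.24 and −0.67, at percentiles 0.02 and 0.36. The spliceosome (302 genes) had 0.055, at percentile 95.9 and not called, and 0.16, at percentile 100. The 18 antenna proteins had −1.69 at 48 h, −2.65 at 25 d against 0 h and −0.63 at 25 d against 48 h, the last at percentile 3.98 and not called. The 64 ethylene-responsive transcription factors had 0.36, 0.26 and −0.044, the last at percentile 91.0 and not called. These values are on the deposited scale.

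For the lower photosystem genes at 48 h, counting error alone is argued against, since the interval lay below 1 in 86.8% of the list, and library scaling too, since the median was −0.74 under median-of-ratios scaling. Sampling at another time of day may have contributed, because the clock list had a median of −0.91 in the same comparison, but that list holds only 5 genes. Of the 116 genes of the KEGG circadian rhythm pathway 2 were at least 2-fold higher and 12 lower, with a median of 0.044, which does not settle the matter. Leaf age cannot be told apart from the virus, with 0 libraries of mock-inoculated leaves, and an effect of the virus stays open and untested.

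Organelle-like names were noticed among the most abundant loci at 25 d, and a list of 29 such names was first written to test whether that group was higher. As a whole the list was not higher. Its median at 25 d against 0 h was −0.55, at percentile 5.68, with 5 genes at least 2-fold higher and 11 lower, and the counting interval lay above 1 in 13.8% of them. The 2 most abundant members at 25 d were higher: Cla000034 had 7908 against 793 FPKM and Cla003063 had 3774 against 539 FPKM. The list also took up proteins such as Ycf20-like ones that nuclear genes encode, so its median does not settle the idea. The loci without a reference gene name were taken up in its place after their values were seen.

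Of those loci without a reference name, 884 were at least 2-fold higher at 25 d than at 0 h. The highest number simulated from counting error was 127. That cannot exclude counting error, because loci kept by the filter through chance reads at 25 d are not covered by the simulation. Over all loci, 189 lone single-exon transcripts at 25 d had the bases of exactly 1 read pair, against 55 at 0 h. Genomic DNA or unspliced RNA in the 25 d library may have contributed. Intronic and pre-mRNA-like transcripts together exceeded reference transcripts by 1.07 in median log2 ratio, but this came from the intronic ones (median 1.47), since the pre-mRNA-like ones had a median of 0.080 against −0.15 for reference transcripts. Single-exon transcripts at unknown loci exceeded multi-exon ones by 1.16. Another sequencing run was not established by the read pairs of 302 bases, and it could not be told apart from the time point. Induced long noncoding RNAs stay open and untested.

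The circRNA total in SRPBM was lower at 25 d. Fewer bases aligned to assembled transcripts per read may account for this, because per aligned base the ratio to 0 h was 1.06 (counting interval 0.688 to 1.57). A fall relative to linear transcripts as large as the ratio of 0.414 to 48 h per read is argued against by the ratio per aligned base, 0.938 (0.609 to 1.39). A smaller fall stays open.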
